A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

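The samples were 6 libraries of mononucleosome-sized DNA from synchronous meiotic cultures of diploid SK1 yeast, at 0, 1, 2 and 3 hr of dataset N1 and 0 and 4 hr of dataset N2. Per the labels' protocols, cells were crosslinked with formaldehyde, spheroplasted and digested with MNase, and DNA of mononucleosome size was cut from a gel and sequenced on Illumina Genome Analyzers. The datasets came from different laboratories and differed in sporulation medium (0.3% potassium acetate in N1, 2% in N2), cell density (optical density near 1.9 and 6.5) and MNase (20 and 40 units), so laboratory, digestion and medium cannot be separated from the dataset. Groups were taken from the sample titles, and each group held 1 library.

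The deposited values are coverage, a whole-number signal for each base pair, per the file headers 1 column per library, with no scaling to depth visible in the values. Beside it stands a deposited column of 0 and 1 named as a mask, whose rule is not given in the sources used here; 12.0% of the 12070898 nuclear positions carry a 1 and were left out of tiles. The aligner, the filters and the genome build are not given in the sources used here. Coordinates are those of the file. Gene annotation in the same coordinates was not used here, because the chromosome lengths of the only gene table at hand (R64) differ from those of the file; genes, promoters, gene lists, profiles around gene starts and distances to replication origins were therefore not analysed here, and regions are named by chromosome and position.

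The way reads were turned into coverage was tested on the file. If each read covers 1 fixed length, the number of reads starting at each position can be recovered by differences and is never negative. A length of 137, 140, 145 and 140 bp at 0, 1, 2 and 3 hr of N1, and 137 bp at 4 hr of N2, gave 0 negative starts on 16 of 16 chromosomes. The length tried for each library was the lag at which rises and falls of coverage matched best. At 0 hr of N2 this was 148 bp, which gave 5719445 negative starts, and other lengths were not tried. Reads were counted as total coverage over the length tried. This gave 1982338, 1656089, 2326382 and 2336718 reads at the successive times of N1 and 4457536 and 4747048 in N2. Coverage cannot show duplicate reads, and the counting intervals given for tiles (exact conditional binomial, 95%) cover counting error only.

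Relative occupancy was the mean coverage of a window divided by the library's mean over all nuclear positions. Tiles of 250 bp with at least 80% of positions unmasked were used, 41618 in all, and the 41229 with a mean relative occupancy of at least 0.1 were tested. Log2 values carry a pseudocount of 0.1, which understates differences of nearly empty tiles. The time trend was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, not robust) on log2 occupancy against hours with the dataset as a block, with 3 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment. limma shares the estimate of spread between tiles, and a p-value measures the scatter of these libraries around a straight line within datasets, which may be technical. Named tiles followed a rule for genes applied to tiles: up to 10 per direction past the trend test with the same sign at 3 hr of N1 and 4 hr of N2, with places left open by the test given to the tiles with the largest smaller of the 2 differences. None passed, so all 20 were chosen by size.

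The trend step was tested on simulated data of 41229 tiles with 100 tiles given each known slope. With counting error and the residual spread of the real fit, it recovered 42% of slopes of 0.3 log2 units per hour. Of slopes of 0.5 it recovered 97%, and there was 1 wrong call. With counting error only, it recovered 77% and 100%, with 0 wrong calls. The residual spread was 1 median value for all tiles and already holds counting error. The first setting therefore counts that error more than once, and differences in spread between tiles were not simulated. Counting error in the spread of differences was simulated from Poisson reads, with allowance for reads that overlap a tile in part.

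Depleted regions were unmasked stretches of 80 to 600 bp with the mean of the 6 libraries under 0.4 per base pair and 200 bp of unmasked sequence on either side. The overlap of extreme tiles was set against 1000 permutations within 100 bins of mean occupancy. The rule for named tiles was also applied 100 times with the N2 values permuted within these bins. Autocorrelation of coverage was taken over nuclear chromosomes from a lag of 100 bp. Long-range differences used 5 kb tiles, and chromosome ends were taken as the outer 20 kb or 50 kb. Standard errors by jackknife leave out 1 chromosome at a time. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

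The tile test, its block, the comparison of 0 hr with later times, the pseudocounts, scalings, filters, tile sizes, omission of each library, the agreement of the datasets and the periodicity were chosen before the data were examined. Depleted regions, re-extension of the reads of the other 5 libraries to the 148 bp of 0 hr of N2, scaling to the surrounding 10 kb in the tile test, the permutations within occupancy bins, the ends set against the interior of chromosomes, the lists of the 0.5% most extreme tiles, the mean of unmasked positions as scale and the removal of the occupancy level were added after the data were seen.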

Results

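Nucleosome positions were mapped in diploid budding yeast of the SK1 background, a strain that sporulates rapidly and in synchrony, during the first hours after transfer to sporulation medium. Crosslinked chromatin was digested with micrococcal nuclease (MNase), which cuts linker DNA between nucleosomes, and mononucleosome-sized DNA was sequenced. Dataset N1 held 4 libraries, taken at 0, 1, 2 and 3 hr. Dataset N2, prepared in another laboratory, held 2 libraries, taken at 0 and 4 hr. Each time point was 1 library, so no comparison of a time with its own 0 hr library has a replicate check. Occupancy is given relative to the mean coverage of the nuclear chromosomes of the same library, which is 1.

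Mean nuclear coverage was 22.5, 19.2, 27.9 and 27.1 at 0, 1, 2 and 3 hr of N1, and 54.7 and 53.9 at 0 and 4 hr of N2. The number of reads that this coverage corresponds to was 1656089 to 2336718 in N1, and 4457536 and 4747048 in N2. A 250 bp tile held on average 34.3 to 48.4 reads in N1 and 92.3 to 98.3 reads in N2. From these numbers, counting error gave an average tile a coefficient of variation of 14.4 to 17.1% in N1 and 10.1 to 10.4% in N2. These percentages make no allowance for reads that overlap a tile in part, whereas the simulated counting error given below does.

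The first question was how far the nucleosome landscape differed between times and between laboratories. Landscapes of the same dataset were much closer to each other than those of different datasets. Across 250 bp tiles of the 16 nuclear chromosomes, Pearson's r of log2 occupancy was 0.885 to 0.954 over the 7 pairs of libraries within a dataset, and 0.544 to 0.679 over the 8 pairs between datasets. The 0 hr libraries of the datasets, which share the nominal time, had r = 0.677 and Spearman's rho = 0.629, and 2227 tiles were higher in N1 by at least 1 on the log2 scale and 1033 were lower. Tiles are not independent replicates, and no p-value was computed for these correlations.

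Depleted tiles were fewer at 2 and 3 hr of N1, and more numerous at 4 hr of N2, than at 0 hr. Tiles with occupancy under 0.5 made up 10.2, 11.9, 8.41 and 7.62% of tiles at 0, 1, 2 and 3 hr of N1, and 14.3 and 15.8% at 0 and 4 hr of N2. The SD of log2 occupancy over tiles was 0.66, 0.68, 0.60 and 0.58 in N1 and 0.76 and 0.81 in N2. These are values of single libraries, and the datasets differed in MNase units, medium and cell density as well as in time. In N1 the libraries with fewer reads had the larger shares and SDs, so depth cannot be told from time there. In N2 the library with more reads had the larger values.

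Between 0 hr and the later times, the spread of tile differences was close to counting error at 1 and 2 hr of N1 and wider at 3 hr of N1 and 4 hr of N2, while large differences were more frequent than counting error gives at all of these times. The SD of the log2 difference from 0 hr was 0.31, 0.27 and 0.31 at 1, 2 and 3 hr of N1, where counting error alone gave 0.29, 0.26 and 0.26, and it was 0.24 at 4 hr of N2, where counting error gave 0.18. At 3 hr of N1, 253 tiles were higher by at least 1 on the log2 scale and 33 were lower, against 32 and 15 in simulated counts with no difference. The numbers were 123 and 105 at 1 hr, against 46 and 79, and 140 and 28 at 2 hr, against 23 and 18. At 4 hr of N2, 59 tiles were higher and 51 were lower by this much, against 0 and 0.

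The 10 tiles with the greatest increase shared by both datasets were higher by at least 1.00 on the log2 scale in each. In 100 permutations of N2 among tiles of like occupancy, the last of 10 tiles chosen in this way reached at most 0.84, and the first 0.82 to 1.78. Low levels at 0 hr came with the choice: 9 of the 10 had occupancy under 0.5 at 0 hr in both datasets, and 7 to 10 did in the permutations. The tile at chromosome IX 395501 to 395750 went from 0.185 at 0 hr through 0.385 and 0.662 to 0.824 at 3 hr of N1, and from 0.259 to 0.836 in N2. The log2 differences were 1.69 in N1 (95% counting interval 0.97 to 3.39) and 1.39 in N2 (1.01 to 2.40). On chromosome IV, the tile at 1269501 to 1269750 went from 0.297 to 0.855 in N1 and from 0.423 to 1.24 in N2. Also on chromosome IV, the tile at 600501 to 600750 stood at 0.103 and 0.101 in the 0 hr libraries, at 0.866 at 3 hr of N1 and at 0.370 at 4 hr of N2. The tile at IV 551001 to 551250 went from 0.208 to 0.578 in N1 and from 0.249 to 1.10 in N2. The tile at II 614001 to 614250 differed between the laboratories in level, at 0.556 and 0.0796 at 0 hr, yet was higher later in both, at 1.43 and 0.312. The other 5 tiles start at IV 591751, XIV 739251, IV 544501, XI 260001 and XVI 585751. The smaller of the 2 log2 differences of each of the 10 tiles was 1.00 to 1.39, and the counting intervals of both datasets excluded 0 in 10 of them, against 2 to 9 in the permutations. Over all tiles, both intervals lay above 0 in 58, against 19 to 44.

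The tiles with the greatest decrease shared by both datasets had smaller differences. The last of these 10 was lower by at least 0.72 in both datasets, against at most 0.66 in the permutations, where the first reached 0.64 to 1.41. At 3 hr of N1 and 4 hr of N2, 8 of the 10 had occupancy under 0.5, as did 3 to 10 in the permutations. The tile at XIII 852001 to 852250 stood at 1.04, 0.668, 0.407 and 0.264 at the successive times of N1, and at 0.403 and 0.122 in N2, with log2 differences of −1.64 (−2.98 to −1.04) and −1.18 (−2.79 to −0.74). The tile at III 133251 to 133500 went from 1.05 to 0.553 in N1 and from 0.767 to 0.127 in N2. The tile at VI 95751 to 96000 had the highest level of the 10, at 3.45 at 0 hr of N1, 1.33 at 1 hr, 1.39 at 2 hr and 2.03 at 3 hr, and at 1.26 and 0.483 in N2. The other 7 start at VIII 56251, X 220751, XIII 469501, XI 456751, II 193501, IV 546001 and V 264251. The counting intervals of both datasets excluded 0 in 8 of the 10, against 0 to 7 in the permutations, and over all tiles both lay below 0 in 34, within the 17 to 43 of the permutations. IV 546001 and V 264251 were not distinguishable from no difference in N1 at this depth.

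The test across the 6 libraries was a linear time trend with the dataset as a block, and it called no tile. limma gave an adjusted p under 0.05 for 0 of 41229 tiles, with a lowest adjusted p of 0.0512, which IX 395501, IV 1269501 and III 133251 had. An unadjusted p under 0.05 was found for 1048 tiles, where chance gives 2061, and limma without its mean-variance trend also called 0. The fit asks for 1 slope shared by both datasets, so differences of opposite sign in N1 and N2 count as scatter. A trend within 1 dataset only is therefore not excluded. Adjusted p in limma was 0.0512 to 0.700 for the 10 named tiles that were higher and 0.0512 to 1.00 for the 10 that were lower, so all 20 were named by size. The count rested on single libraries: it was 1 without N1 0 hr, 15 without N1 1 hr, 11 without N1 3 hr, 17 without N2 0 hr and 15 without N2 4 hr, and stayed at 0 without N1 2 hr.

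Set against all later times together, the 0 hr libraries differed at 18 tiles, of which 17 rose and 1 fell by limma with the same block. Of the named tiles that were higher, 7 were among them, with limma adjusted p of 0.00375 at IV 600501 and at IV 551001, 0.00475 at II 614001, 0.00525 at XI 260001, 0.00945 at IV 1269501, 0.0208 at IX 395501 and 0.0341 at IV 544501. The tile that fell was VI 95751, also a named tile, with a limma adjusted p of 0.000925. Named tiles had been chosen for large differences from 0 hr in libraries that this test also used. Their overlap with its calls is therefore no independent support. The comparison rests on 1 library at 0 hr in each dataset and was not repeated with libraries left out. By limma, 1740 tiles had an unadjusted p under 0.05 in it, where chance gives 2061. The following tiles were picked after their values were seen. On chromosome XI, 3 adjacent tiles from 382751 to 383500 rose together: the first went from 0.475 at 0 hr to 1.56, 1.49 and 1.61 in N1 and from 1.49 to 2.77 in N2 (limma adjusted p = 0.000158). The tile at XII 677751 to 678000 rose from 0.336 to between 1.11 and 1.45 in N1 and from 0.752 to 1.37 in N2 (limma adjusted p = 0.00123), and the tile at XV 671501 to 671750 from 0.206 to between 0.841 and 1.04 in N1 and from 0.257 to 0.597 in N2 (limma adjusted p = 0.00243).

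**Figure D1:**
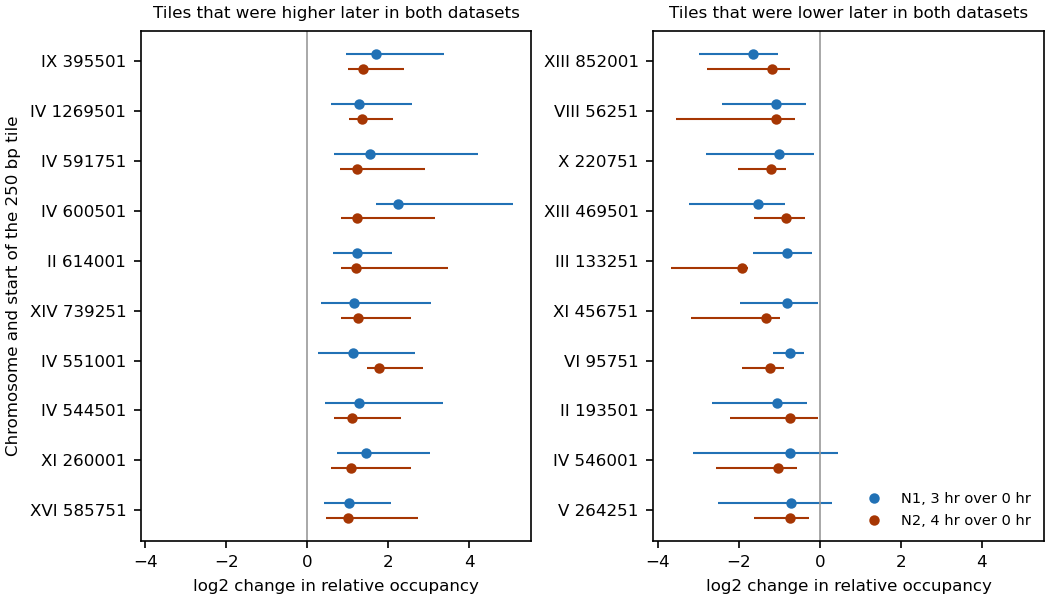
Log2 difference in relative occupancy (x axis, with a pseudocount of 0.1) at the 10 tiles of 250 bp named as higher (left) and the 10 named as lower (right) later in both datasets, listed on the y axis by chromosome and start; points are 3 hr over 0 hr of N1 (blue) and 4 hr over 0 hr of N2 (brown). Lines are 95% counting intervals of the ratio without pseudocount, which lies farther from 0 than the points; they exclude 0 in both datasets for 10 tiles on the left and 8 on the right.

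The next question was whether the datasets repeated each other over the whole genome. They did not: across all 41229 tiles the differences ran weakly in opposite directions, while the most extreme tiles overlapped more than independent lists would in 3 of 4 combinations of directions. Pearson's r between the log2 difference at 3 hr of N1 and that at 4 hr of N2 was −0.107 (jackknife SE over chromosomes 0.00768) and Spearman's rho was −0.129. Counting error alone gave SDs of 0.26 at 3 hr of N1 and 0.18 at 4 hr of N2, where 0.31 and 0.24 were observed. It weakens a correlation of either sign. At 1 hr of N1 the sign turned, with r = 0.0427, and at 2 hr it was −0.0310. Differences also went with the level of the tile, with r = −0.351 at 3 hr of N1 and 0.198 at 4 hr of N2, and with the level removed the datasets had r = −0.0431. Among the 0.5% of tiles, 206 in number, with the greatest increase in each dataset, 20 were shared, where independent lists would share 1.03. Among the 206 with the greatest decrease, 9 were shared. Of the 206 with the greatest increase in N1, 17 were among those with the greatest decrease in N2, and 1 tile went the other way. Permutations among tiles of like occupancy reached at most 10 shared increases, 7 shared decreases and 17 in the first opposite direction. The times differ, and a laboratory effect is not separable from the dataset.

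Nucleosome-depleted regions, which in yeast are found mostly at promoters and are where most meiotic DNA breaks form, stood higher at 2 and 3 hr of N1, and lower at 4 hr of N2, than at 0 hr. These regions were defined after the data were seen, as stretches of 80 to 600 bp in which the mean of the 6 libraries stayed under 0.4. There were 4670 of them, with a median width of 138 bp, covering 764 kb. Their mean occupancy was 0.202, 0.196, 0.235 and 0.251 at 0, 1, 2 and 3 hr of N1, which is 0.971, 1.16 and 1.24 times the 0 hr level (jackknife SE over chromosomes 0.0105, 0.00961 and 0.0110). In N2 it was 0.182 at 0 hr and 0.139 at 4 hr, a ratio of 0.763 (SE 0.00554). The regions were higher than at 0 hr on 4, 16 and 16 of the 16 chromosomes at 1, 2 and 3 hr of N1, and on 0 of 16 in N2. The SE covers the spread between chromosomes of the same libraries, not between cultures, and the difference between datasets was not tested. With reads re-extended to 148 bp, the ratios were 0.956, 1.09 and 1.20 at 1, 2 and 3 hr of N1 and 0.841 in N2. Part of the differences thus went with read length. Reads of 0 hr of N2 could not be recovered at the length tried and were left as they were.

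Of the 4670 depleted regions, the 4294 with a mean relative occupancy of at least 0.1 were tested. By limma, 2 rose with time and 0 fell. The region at XIII 661795 to 661892 stood at 0.0431, 0.109, 0.316 and 0.316 in N1 and at 0.0853 and 0.652 in N2, with a slope of 0.53 ± 0.10 (SE) log2 units per hour and a limma adjusted p of 0.00134. The region at VI 135916 to 136027 stood at 0.152, 0.210, 0.463 and 0.633 in N1 and at 0.0310 and 0.358 in N2, with a slope of 0.49 ± 0.10 and a limma adjusted p of 0.00314. The next in order was IV 542452 to 542592, from 0.0854 to 0.290 in N1 and from 0.0304 to 0.338 in N2, which did not pass (limma adjusted p = 0.0725). Without N2 0 hr or without N2 4 hr, which leaves the trend to N1 alone, 0 regions passed. The count was also 0 without the dataset block and with depletion defined as under 0.3, 4 with median scaling, all higher, and 9 with depletion under 0.5, of which 6 rose and 3 fell. With 0 hr set against all later times, 2 rose and 1 fell. At an unadjusted p under 0.05 there were 212 regions, where chance gives 215, and limma without its mean-variance trend called 2. This fit too asks for 1 slope shared by both datasets, in which the mean of these regions went opposite ways.

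Nucleosomes were regularly arrayed beside the depleted regions in all 6 libraries. Averaged over 8434 flanks, the first peak lay 105 to 110 bp from the edge in N1 and 117 to 120 bp in N2. It reached 1.14, 1.18, 1.14 and 1.21 at 0, 1, 2 and 3 hr of N1, and 1.03 at both times of N2. The edges were set on the mean of the 6 libraries, 4 of them from N1. Differences between the datasets in the place and height of this peak may therefore come from that definition. The trough after the first peak was at 0.924, 0.928, 0.943 and 0.919 in N1, and at 0.893 at 0 hr and 0.841 at 4 hr of N2, the deepest of the 6. The third peak was at 1.25 at 4 hr of N2 and at 1.14 to 1.20 in the other libraries. Over the nuclear chromosomes, the autocorrelation of coverage peaked at lags of 336, 337, 341 and 340 bp in N1 and at 339 and 330 bp in N2. The spacing of its following peaks was 164 to 168 bp in N1, 172 bp at 0 hr of N2 and 162 bp at 4 hr of N2. Read lengths differed between libraries, and these lags were not recomputed with reads of a common length.

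**Figure D2:**
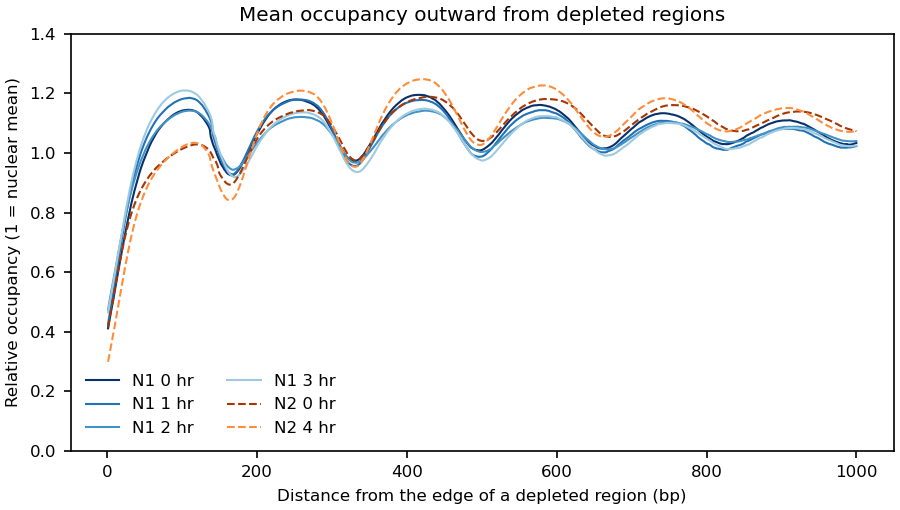
Mean relative occupancy (y axis, nuclear mean 1) by distance in bp from the edge of a depleted region (x axis) over 8434 flanks, with solid blue lines for N1 and dashed brown and orange lines for N2. The first peak is at 1.14 to 1.21 in N1 and 1.03 in N2, and 4 hr of N2 has the deepest first trough, at 0.841. Edges were set on the mean of the 6 libraries, 4 of them from N1.

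Cells copy their DNA before the meiotic divisions, which can move coverage over kilobases, so long-range differences were examined in 5 kb tiles. At 2 hr of N1, neighbouring stretches of chromosome departed from 0 hr together. The autocorrelation of the log2 difference between tiles 20 kb apart was 0.246 at 2 hr of N1, where 300 shuffles of tile order gave −0.0232 to 0.0864. In 2 kb tiles it was 0.121 at the same distance. It was 0.0235 at 1 hr and 0.0362 at 3 hr of N1 and 0.0385 at 4 hr of N2, each within its own shuffles. The 2 hr library also stood apart when set against its neighbours in time, at 0.110 for 2 hr over 1 hr and 0.220 for 3 hr over 2 hr. The difference of 2 hr over 1 hr and that of 3 hr over 0 hr, which share no library, had r = 0.311 across 5 kb tiles. Against 4 hr over 0 hr of N2, which also shares no library, 2 hr over 1 hr had r = −0.333 and 2 hr over 0 hr had r = −0.159.

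The sizes were small. After smoothing over 25 kb, 5% of windows at 2 hr over 0 hr of N1 lay below −0.10 and 5% above 0.09 on the log2 scale, a range of 0.20. This range was 0.14 at 1 hr and 0.16 at 3 hr of N1, 0.16 at 4 hr of N2 and 0.29 between the 0 hr libraries of the datasets, so 2 hr stood apart in how far along the chromosome its differences extended more than in their size. Set against the mean of 1 and 3 hr, the highest windows at 2 hr were XII 630001 to 655000 at 0.16, II 220001 to 245000 at 0.16 and X 670001 to 695000 at 0.14. The lowest were X 15001 to 40000 at −0.13, XVI 170001 to 195000 at −0.12 and IV 1255001 to 1280000 at −0.11. These windows were picked for their values and come from 1 library.

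**Figure D3:**
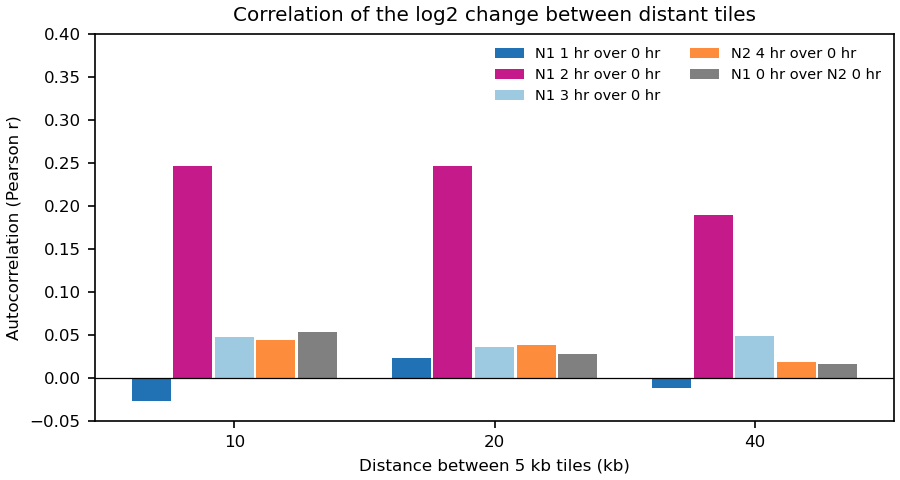
Autocorrelation (y axis, Pearson's r) of the log2 difference in coverage between 5 kb tiles 10, 20 and 40 kb apart (x axis); bars are 1, 2 and 3 hr over 0 hr of N1, 4 hr over 0 hr of N2, and the 0 hr libraries of N1 over N2. Only 2 hr of N1 stands out, at 0.246 for 20 kb (0.121 in 2 kb tiles, not drawn), and the other 4 are at 0.0235 to 0.0385 at that distance.

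Short chromosomes carried higher mean coverage than long ones in every library. At 0 hr of N1, the mean over unmasked tiles was 1.17 on chromosome III, 1.16 on I and 1.10 on VI, against 1.04 on IV and 1.01 on XVI. At 0 hr of N2 the same chromosomes stood at 1.18, 1.15, 1.14, 1.01 and 1.02. Across the 16 chromosomes, r with log10 length was −0.826 to −0.876 over the 6 libraries, and −0.691 to −0.801 without I and III. Within 20 kb of chromosome ends, the mean log2 difference at 3 hr of N1 was 0.06 ± 0.07 (SD over chromosomes) and at 4 hr of N2 it was 0.02 ± 0.06. Set against the part of the same chromosome over 50 kb from an end, the ends were higher by 0.05 ± 0.02 (SE over chromosomes) at 3 hr of N1, on 12 of 16 chromosomes, and by 0.07 ± 0.02 at 4 hr of N2, on 15 of 16. At 1 and 2 hr of N1 this difference was 0.02 ± 0.02 and 0.01 ± 0.01, on 11 and 9 chromosomes.

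**Figure D4:**
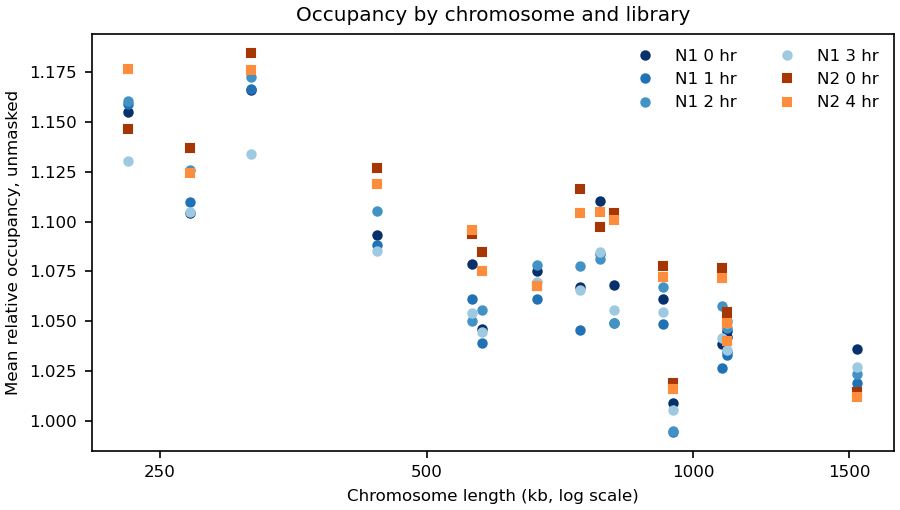
Mean relative occupancy of unmasked tiles (y axis, not starting at 0) against chromosome length in kb (log x axis); each point is 1 of the 16 chromosomes in 1 library, with circles for N1 and squares for N2. Longer chromosomes have lower values in all 6 libraries, with r of −0.826 to −0.876.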

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

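No test was run on the values here, and the plasmid level was read only after the data were seen. The lag of the first autocorrelation peak of nuclear coverage was longer at the later times of N1 and shorter at 4 hr of N2 than at 0 hr. It was 336 bp at 0 hr of N1 and 337, 341 and 340 bp at 1, 2 and 3 hr, and 339 bp at 0 hr of N2 and 330 bp at 4 hr. The spacing of the following peaks was 166.5, 164.5, 167.5 and 163.5 bp in N1 and 172 and 161.5 bp in N2. By this measure 3 hr of N1 and 4 hr of N2 both lay below their 0 hr. The difference between the datasets was not tested. At 0 hr of N2, reads could not be recovered at the length tried. Read lengths were 137, 140, 145 and 140 bp in N1, and 148 bp (the length tried) and 137 bp in N2. The lags were not recomputed with reads of a common length, so a change in nucleosome spacing cannot be told from a difference in read length.

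Sequences outside the nuclear chromosomes carried coverage in all 6 libraries. Mitochondrial coverage was 2.43, 6.58, 2.08 and 3.33% of the mean of unmasked nuclear positions at 0, 1, 2 and 3 hr of N1, and 0.109 and 0.0784% at 0 and 4 hr of N2. The plasmid of 6318 bp was covered at 11.4, 14.1, 11.3 and 12.0 times that mean at the same times of N1, and at 11.0 and 10.3 times in N2. The 1 hr library of N1 was the highest for both.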

How the results depend on the processing

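Alternatives on read extension, local and unmasked scaling of tiles, occupancy level and depleted regions were chosen after the results were seen. The count of 0 tiles became 4 with a pseudocount of 0.5, 2 with median scaling, 18 with 0 hr against later times, 3 with reads re-extended, 1 with local scaling and 3 with the unmasked mean; leaving out 1 library gave 0 to 17. It stayed at 0 with a pseudocount of 0.02, quantile scaling, no filter, a filter of 0.3, no block, no mean-variance trend, and tiles of 150 or 500 bp. The count of 2 depleted regions became 4 with median scaling, 0 without the block, 0 with depletion under 0.3 and 9 under 0.5; leaving out 1 library gave 0 to 3. Omitting a library of N2 leaves the trend to N1.

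The ratio of depleted regions to 0 hr kept its direction throughout: with reads re-extended it was 1.09 at 2 hr and 1.20 at 3 hr of N1 and 0.841 in N2, and with depletion under 0.3 it was 0.676 in N2. With depletion under 0.5 it was 1.22 at 3 hr of N1 and 0.832 in N2. The correlation of the datasets turned to 0.0427 with 1 hr of N1, and was −0.0310 with 2 hr and −0.0431 with the level removed. Similarity of the 0 hr libraries was 0.671 in 150 bp tiles, and the 2 hr autocorrelation was 0.121 in 2 kb tiles. Why these values moved with the setting was not tested. Explanations of the correlation and of the 2 hr structure are taken up below.

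Of the log2 differences of named tiles under other pseudocounts or median scaling, 99 stayed within their counting interval and 21, all with a pseudocount of 0.5, which pulls differences toward 0, did not; none turned. Alternatives chosen for genes, promoters, gene bodies, gene lists, profiles around gene starts and distance to origins were not run. Depth limits tiles of low occupancy most, where a tile of N1 can rest on 4 reads.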

Other observations

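Tests on the removal of the occupancy level and on the difference between laboratories at long range were chosen only after the result was seen. Some unmasked stretches had no coverage in any library. There were 31 such stretches of at least 500 bp on 10 chromosomes, 70365 bp in all, and 17 lay within 50 kb of a chromosome end. Whether the SK1 genome holds these stretches was not examined. The longest was XV 3241 to 10906, at 7666 bp. Chromosome XII carried 3 of exactly 3232 bp, at 469083 to 472314, 482315 to 485546 and 485967 to 489198. The masked block just before the first of these, XII 460030 to 469082, was covered at 2.27, 3.25, 2.42 and 3.08 times the nuclear mean at 0, 1, 2 and 3 hr of N1, and at 1.16 and 1.30 times at 0 and 4 hr of N2.

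The differences from 0 hr ran in opposite directions in the datasets across tiles, with r = −0.107. With reads re-extended to the 148 bp tried for 0 hr of N2, r was −0.0979 (SE 0.00788). This argues against unequal read lengths in N1 as the whole cause. Reads of 0 hr of N2 could not be recovered at 148 bp and were left as they were, so unequal lengths within N2 are not excluded. Dependence of the difference on occupancy could account for part, since removing it left r = −0.0431 (SE 0.00642), which is nearer to 0 but still below it. Laboratory, MNase units, medium and time all differ between the datasets and cannot be told apart here, and no biological explanation was tested.

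The long-range structure at 2 hr of N1 may be a trace of DNA replication under way, as cells copy their DNA before the meiotic divisions. A bias of the kind that separates the laboratories also stays open: their 0 hr libraries differed with an autocorrelation of 0.0275 (SE 0.0192) at 20 kb, against 0.246 (SE 0.0386) at 2 hr, but over a wider spread. The autocovariances, 0.000942 (SE 0.000654) and 0.00214 (SE 0.000313), were less than 2 SE of their difference apart, and 2 hr over 1 hr had r = −0.223 with the laboratory difference. If ends were copied late, the outer 50 kb of at least 13 of 16 chromosomes should have lain below the rest at 2 hr. Against the mean of 1 and 3 hr, 11 did. The ends at 3 hr were themselves higher than at 0 hr relative to the interior, by 0.05 on 12 of 16 chromosomes. Against 0 hr, the outer 20 kb at 2 hr were not lower than the interior, at 0.01 ± 0.01, with 9 of 16 higher. These values leave replication open. A bias of the 2 hr library alone is open too, since there is 1 library at this time.

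The tiles with the greatest differences may mark places where nucleosomes were gained or lost in both cultures. An overlap set by occupancy level alone is argued against for increases. The 20 shared exceeded the 10 that 1000 level-matched permutations reached at most, and the 9 shared decreases exceeded 7. Permuted tiles were matched on mean occupancy only, so noise of tiles that vary more than others of like occupancy is not excluded. In the same lists 17 tiles were among the greatest increases of N1 and decreases of N2, which the permutations also reached. Among the 2061 greatest of each kind, 189 increases were shared (permutations 90 to 156) and 107 decreases (68 to 124). In that wider set 222 tiles were lower in N1 and higher in N2, above the 76 to 131 of permutations. A further 271 were higher in N1 and lower in N2 (224 to 294). Shared decreases in the wider set thus lay within the permutations, while an opposite direction exceeded them. An excess over the permutations therefore does not by itself show a shared gain or loss.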
